A study of Mus musculus with 22 samples.

How the data were processed

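RNA was sequenced from 14 samples of mouse ES cells, 2 replicates in each of 7 groups: WT and TKO cells, WT cells after knock-down of HP1alpha, HP1beta, HP1gamma or all 3, and TKO cells after knock-down of all 3. Per the labels' protocols, cells were grown on gelatin with leukaemia inhibitory factor and without feeder cells, knock-downs were made by siRNA transfection 48 h before RNA extraction, WT and TKO libraries were 50-base single-end reads from a Genome Analyzer, and knock-down libraries were 101-base paired-end reads from a HiSeq. The series also holds 2 bisulfite and 6 MNase samples, which were not analysed here.

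The submitters' processing notes name TopHat2, Bowtie2 and the mm10 build for the RNA samples; versions and settings are not given in the sources used here. Per the labels, 1 splicing summary stands for both replicates of a group, so the authors pooled the replicates before deposit. Per the file headers, the summaries are MISO output for skipped exons; the MISO version and its event annotation are not given in the sources used here. The deposited inclusion level is a fraction (0 to 1), the posterior mean of the share of transcripts that include the exon, computed by the authors with MISO. How each class of reads enters this level could not be examined. Per the file headers, each event also carries the bounds of an interval, whose level is not stated, and the count of reads that fit the inclusion isoform alone, the skipping isoform alone, both or neither. Every deposited event has at least 100 reads over these classes, so genes and exons below that depth are missing from a library's list.

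Exons were joined between libraries by their event coordinates. Gene symbols came from the GRCm38.p6 gene table: the gene whose span holds the whole event, on either strand, with predicted genes giving way to other protein-coding ones. Of 10873 events 10521 lay in 1 gene, 248 in none and 104 in several. All 10873 were kept for counts, and an event of several genes is named as such. Events in near-identical gene copies cannot be told apart by these reads.

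Per exon, reads for inclusion alone and for skipping alone were compared between 2 libraries with a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the exons that had at least 20 such reads in each library. An exon was called at an adjusted p of at most 0.05 with an absolute difference in the deposited inclusion level of at least 0.1. The 7 comparisons were TKO against WT, each of 4 knock-downs in WT cells against WT, the triple knock-down in TKO against TKO, and TKO against WT under the triple knock-down. Each test used only the libraries it compares. The dependence of the knock-down difference on the cell line was tested with Zelen's exact test of equal odds ratios, called at an adjusted p of at most 0.05. The 21 pairs of libraries were also compared over 4313 exons that passed the read minimum in all 7, with reads thinned per exon to the shallowest library in 10 draws. Overlap with a shared WT library was set against independent lists and against 100 simulated sets of unchanged libraries. Exon features were set against 10000 random sets of tested exons. GC and CpG content were not analysed here, since they need a genome sequence.

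The choices of tests, thresholds, lists and the rule for named genes were made before the data were examined. The rule named, per comparison, called exons whose deposited intervals did not overlap, 1 exon per gene: the 10 largest increases and 10 largest decreases for TKO and for the triple knock-down against WT, and 4 of each otherwise. It added up to 10 called members of the gene lists by absolute difference, the event with most reads of the HP1 and Dnmt genes, and the 5 largest differences of log2 odds ratio per direction. Some exons that the rule named are not reported here. The 10 lists were HP1 genes, DNA methyltransferases, SR proteins, hnRNP and other splicing regulators, chromatin and DNA methylation regulators, pluripotency genes, cytoskeleton, adhesion and polarity genes, germline genes silenced by promoter methylation, differentiated and fibroblast markers, and interferon and siRNA response genes. A list's median absolute difference was placed among 10000 random lists of the same size matched on informative reads but not on inclusion level, as a description of these libraries. Event reads per gene, the largest event of a gene scaled to the event reads of the library (RPM), were given with exact Poisson 95% intervals and no test.

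Median width of the deposited interval was 0.09 in WT and TKO and 0.15 to 0.18 in the knock-downs. Simulated data with known changes in the share of inclusion among distinguishing reads were used to test the calls. The changed exons had mid-range shares. Deposited levels and a shift between platforms were not simulated, so the recoveries do not describe the actual calls of knock-downs against untransfected cells. Of 100 changes of 0.2 in this share per comparison, 46 were recovered for TKO against WT. For the HP1alpha, HP1beta, HP1gamma and triple knock-downs 35, 39, 32 and 36 were recovered. The triple knock-down in TKO gave 36, and TKO against WT under the triple knock-down 25. Of 100 changes of 0.1, 12, 4, 5, 4, 4, 9 and 4 were recovered in the same order. PCR duplicates are not marked, so reads are not certain to be independent molecules.

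Alternatives were a difference of at least 0.2, a false discovery rate of 0.01, minimums of 10 and 50 reads, non-overlapping deposited intervals in place of the test, an absolute log2 odds ratio of at least 1 in place of the difference, thinned reads, exons that pass in all 7 libraries, 1 event per exon, reads of both classes over the compared libraries, and event reads scaled to exons listed in all 7 libraries. Added after the data were seen were a read of each class in each library, a null odds ratio set to the median of exons in the same eighth of exon length with at least 5 reads of both classes, and agreement in direction between read odds and deposited level. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.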

Results

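Alternative splicing was measured by RNA sequencing in mouse embryonic stem (ES) cells that differed in DNA methylation and in heterochromatin protein 1 (HP1), a family of chromodomain proteins that bind methylated histone H3. The study asked whether HP1 takes part in the effect of DNA methylation on alternative splicing. The 14 RNA samples fall into 7 groups of 2 replicates. R1 cells are the wild type, here WT. TKO cells lack the DNA methyltransferases encoded by Dnmt1, Dnmt3a and Dnmt3b. Any other difference between the WT and TKO cell lines is not separated from that loss in these comparisons. WT cells were also transfected with siRNA against HP1alpha (gene Cbx5), HP1beta (gene Cbx1) or HP1gamma (gene Cbx3) at 90 nM, or against all 3 at 60 nM each, here the triple knock-down. TKO cells received the same 3 siRNAs at 80, 80 and 120 nM. RNA was taken 48 h after transfection. The authors pooled the replicates of each group before deposit, so there was 1 pooled library per group and no replicate measurement. Every test therefore compares libraries, not conditions. Intervals of read counts cover counting error only, and intervals of shares of exons treat exons as independent draws, which they are not. No interval covers the spread between replicates.

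The deposited values are inclusion levels, the share of transcripts (0 to 1) that include a cassette exon, with an interval and with the reads behind each level. Reads counted over exon events numbered 25941844 in WT and 25200437 in TKO. The knock-down libraries were shallower, with 9750348 for HP1alpha, 8907552 for HP1beta, 7383028 for HP1gamma, 4677236 for the triple knock-down and 7571677 for the triple knock-down in TKO. The median number of reads that distinguish inclusion from skipping was 96 per exon in WT, 100 in TKO and 48 to 66 in the knock-downs. WT and TKO were sequenced as 50-base single-end reads without transfection, while all knock-downs were 101-base paired-end libraries of transfected cells. No group with a control siRNA is labelled, so knock-down, transfection and platform coincide in every comparison of a knock-down with untransfected cells. The 10873 events cover 10148 distinct exons in 5296 genes, with mm10 coordinates.

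The targeted genes were examined first. Cbx5, read at its exon event on chromosome 15 (103215022 to 103215121), had 43.0 RPM (reads of the event scaled to the event reads of the library; 95% exact Poisson interval 39.0 to 47.3) in the HP1alpha knock-down, against 110 and 105 in the HP1beta and HP1gamma knock-downs. That is a ratio of 0.399 (0.358 to 0.444) to those 2 libraries pooled. Cbx1 (chromosome 11, 96806616 to 96806764) stood at a ratio of 0.324 (0.314 to 0.334) in the HP1beta knock-down, and Cbx3 (chromosome 6, 51478438 to 51478600) at 0.634 (0.547 to 0.731) in the HP1gamma knock-down. In the triple knock-down the ratios to the single knock-downs that did not target the gene were 0.522, 0.352 and 0.710 for Cbx5, Cbx1 and Cbx3, and in the triple knock-down of TKO cells they were 0.468, 0.641 and 0.691. Cbx3 had 457 RPM in WT and 480 in TKO but 32.2 to 52.2 in all 5 knock-down libraries, including those in which it was not targeted. Cbx1 had 615 in WT and 1522 and 1625 in the HP1alpha and HP1gamma knock-downs, so event reads are not comparable between the untransfected and the knock-down libraries. Between libraries of one platform, Dnmt3a (chromosome 12, 3896578 to 3896685) stood at a ratio of 0.450 (0.415 to 0.488) in TKO to WT and Dnmt3b (chromosome 2, 153670849 to 153670908) at 0.157 (0.150 to 0.164). Whether these exons lie in the deleted parts is not given in the sources used here, and no event of Dnmt1 was listed.

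**Figure D1:**
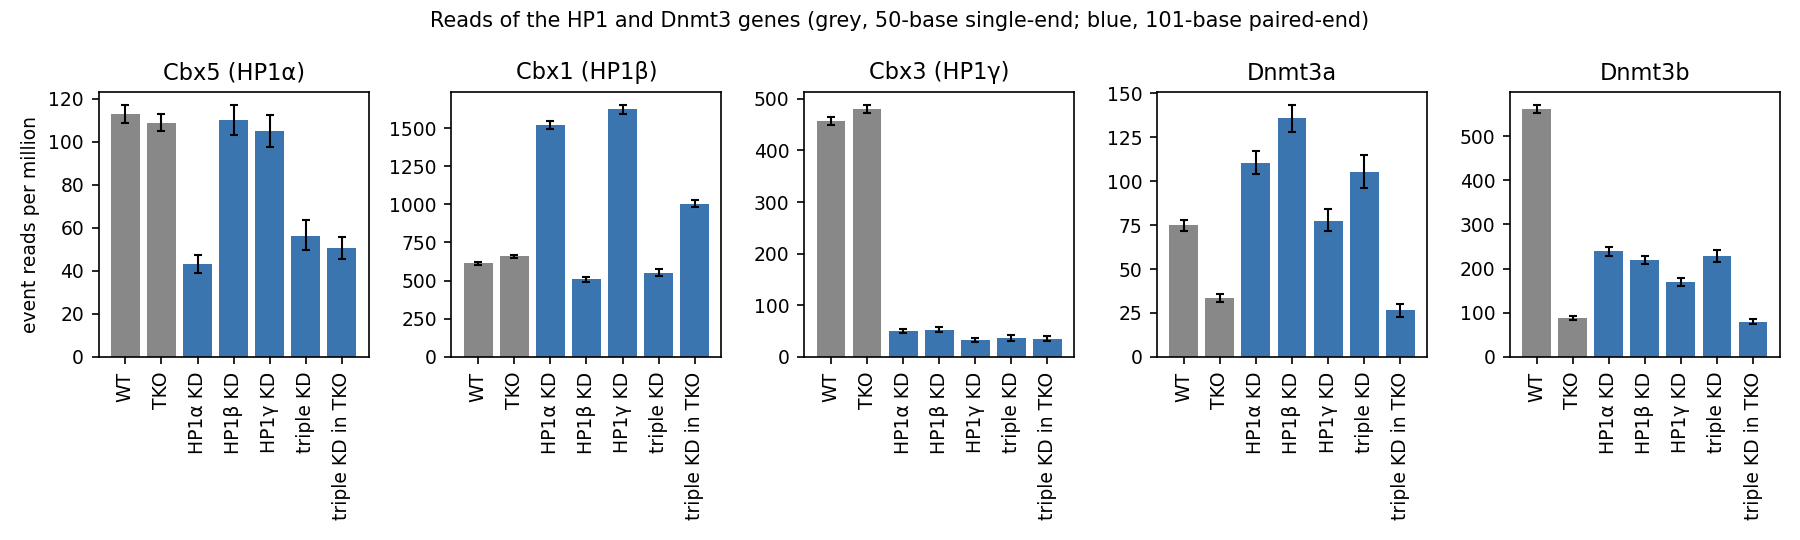
Event reads in RPM of Cbx5, Cbx1, Cbx3, Dnmt3a and Dnmt3b (1 panel each) in the 7 libraries; bars are values, error bars exact Poisson 95% intervals, grey bars are 50-base single-end and blue bars 101-base paired-end libraries. Cbx5 stands at 43.0 in the HP1alpha knock-down against 110 and 105 in the other single knock-downs, and Dnmt3b at 88.1 in TKO against 562 in WT.

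The difference between TKO and WT cells was examined first without transfection. Inclusion was higher in TKO at exons of Tbl1xr1, a subunit of nuclear corepressor complexes, of Dnm2, the dynamin that severs endocytic vesicles, and of the tyrosine kinase Src. The Tbl1xr1 exon (chromosome 3, 22089413 to 22089522) was included at 0.90 (deposited interval 0.74 to 1.0) in TKO and 0.20 (0.11 to 0.32) in WT, with adjusted p = 1.2e-06 by Fisher's exact test. A 12-nucleotide exon of Dnm2 (chromosome 9, 21490658 to 21490669) rose from 0.02 to 0.53, on 0 inclusion and 45 skipping reads in WT and 64 and 45 in TKO (adjusted p = 9.53e-12, Fisher's exact test). Inclusion was lower at exons of Ddias, a suppressor of apoptosis after DNA damage, of Macf1, which links microtubules and actin, and of Tia1, an RNA-binding regulator of splicing and translation. The Ddias exon (chromosome 7, 92868112 to 92868190) fell from 0.95 (0.85 to 1.0) to 0.50 (0.44 to 0.56), with adjusted p = 3.35e-18 in the same exact test, on 110 inclusion and 0 skipping reads in WT and 148 and 103 in TKO.

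Among 7695 tested exons 245 were called higher and 107 lower in TKO, 4.57% together (exact 95% interval 4.12 to 5.07), in 302 genes. The median absolute difference of called exons was 0.17. The 10 largest increases with intervals apart, given as WT to TKO, were in Tbl1xr1, Fam53c (0.39 to 0.93), Dnm2, Traf3 (0.30 to 0.81), Szrd1 (0.46 to 0.96), Pym1 (0.07 to 0.57), Src (0.35 to 0.82), Dedd (0.49 to 0.95), Ankrd16 (0.35 to 0.80) and Tsc22d1 (0.26 to 0.70). Traf3 is an adaptor of tumour necrosis factor receptors and its exon overlaps 4930595D18Rik. Pym1 removes exon junction complexes from spliced mRNA. The 10 largest decreases were in Tctex1d2 (0.92 to 0.36), Phkb (0.87 to 0.35), Ddias, Macf1 (0.80 to 0.38), Rnf146 (0.96 to 0.55), Tia1 (0.71 to 0.30), Pitpnm2 (0.89 to 0.49), Lpgat1 (0.41 to 0.02), Btrc (0.91 to 0.53) and Gjc1 (0.89 to 0.53). Of the called exons, 143 lacked inclusion or skipping reads altogether in one of the libraries. That holds for most of the exons named here: 8 of the 10 decreases (all but Macf1 and Lpgat1) had 0 skipping reads in WT, and 6 of the 10 increases (Tbl1xr1, Fam53c, Szrd1, Dedd, Ankrd16 and Tsc22d1) had 0 in TKO. With the odds ratio expected under no change set by exon length, an adjustment chosen after the data were seen, the split was 198 higher and 139 lower.

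Regulators of chromatin and DNA methylation had the highest percentile among the gene lists. Of their 152 exons in 56 genes 6 were called higher, 4 lower and 142 not called, 11 when adjusted over the list alone. Their median absolute difference lay at percentile 99.98 of 10000 random lists matched on reads. That median was 0.03, against 0.02 over all tested exons and 0.02 in the hnRNP and SR protein lists below. The random lists were drawn by exon and so do not allow for several exons of 1 gene. An exon of the histone demethylase gene Kdm6a (X chromosome, 18246975 to 18247109) rose from 0.60 (0.53 to 0.69) to 0.95 (0.88 to 1.0), with adjusted p = 1.86e-06 in Fisher's exact test, on 132 inclusion and 22 skipping reads in WT and 168 and 0 in TKO. An exon of the chromatin remodeller Atrx (X chromosome, 105911470 to 105911654) rose from 0.18 (0.13 to 0.23) to 0.44 (0.36 to 0.52). Chromatin genes with a lower exon included Ncor1 (0.79 to 0.63) and Ehmt2 (0.42 to 0.23), which the rule for named genes left out and which were added after their values were seen, as were all further members named to spell out a small count. Of 122 exons of hnRNP genes and other splicing regulators 7 were called higher, 2 lower and 113 not called, 9 when adjusted over the list alone (percentile 97.6), with Rbm5 rising from 0.54 to 0.82 and Tia1 and Hnrnpc (0.31 to 0.16) the lower ones. SR protein exons numbered 50, with 1 higher (Clk4, a kinase of SR proteins, 0.49 to 0.70), 1 lower (Luc7l, 0.17 to 0.04) and 48 not called, 3 when adjusted over the list alone (percentile 96.1).

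For the cytoskeleton, adhesion and polarity list the counts were 22 higher, 7 lower and 236 not called of 265 exons, 32 when adjusted over the list alone, at percentile 74.6. Tcl1, a coactivator of Akt in ES cells, was the called member of the pluripotency list (0.68 to 0.91), with 1 exon higher and 14 not called, 3 when adjusted over the list alone (percentile 45.4). Stk31 was the called member of the germline list (0.69 to 0.38), with 1 exon lower and 6 not called, 1 when adjusted over the list alone (percentile 21.4). None was called for HP1 genes (4 exons, percentile 89.3), DNA methyltransferases (3, percentile 94.3), differentiated and fibroblast markers (7, percentile 54.7) or interferon response genes (8, percentile 75.3), with 0 when adjusted over the list alone in each. Event reads of the differentiated and fibroblast markers were higher in TKO than in WT, with a median log2 ratio of 1.25 over 5 genes.

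Loss of HP1 in methylated cells was examined with the triple knock-down against WT. Inclusion was higher in the knock-down at very short exons of the adhesion receptor gene Adgrl1 and of Commd6, and at exons of Morf4l1, a chromodomain protein, and Rps24, a ribosomal protein. The 18-nucleotide Adgrl1 exon (chromosome 8, 83937916 to 83937933, overlapping Gm10644) stood at 0.96 (0.91 to 0.99) against 0.02 (0 to 0.07), with adjusted p = 8.8e-24 by Fisher's exact test. The 20-nucleotide exon of Rps24 (chromosome 14, 24495430 to 24495449) stood at 0.82 (0.77 to 0.86) against 0.21 (0.19 to 0.22), with adjusted p = 4.15e-52 in the same exact test. Inclusion was lower at exons of Tpt1, the translationally controlled tumour protein, Ctnnd1, the p120 catenin of cell junctions, and Tra2a, an activator of exon inclusion. The Ctnnd1 exon (chromosome 2, 84624270 to 84624449) stood at 0.05 (0.03 to 0.07) against 0.67 (0.64 to 0.70) and the Tra2a exon (chromosome 6, 49252803 to 49253108) at 0.10 (0.09 to 0.12) against 0.68 (0.66 to 0.70), with adjusted p = 3.51e-28 and 2.4e-67 in the exact test.

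Of 4591 tested exons 84 were called higher and 430 lower, 11.2% together. The exact test takes an odds ratio of 1 as no change. Yet WT had 6.25 inclusion reads per skipping read and the triple knock-down 3.22. Among exons with at least 5 reads of each class, the median log2 odds ratio was -0.157 in the shortest eighth and -1.105 in the longest. It was negative in every eighth of each knock-down comparison with untransfected cells. Part of this split and of the p-values may therefore be a shift common to most exons. The largest increases, given as WT to knock-down, included Adgrl1, Commd6 (0.03 to 0.91), Morf4l1 (0.10 to 0.89), Rbm3 (0.19 to 0.86), Rps24, Atp5c1 (0.39 to 0.96), Eif4a3 (0.49 to 0.96), Dkc1 (0.25 to 0.72) and Tdh (0.44 to 0.90). Tdh encodes threonine dehydrogenase and its exon overlaps Gm17232; its reads, 909 for inclusion and 12 for skipping against 764 and 0 in WT, point the opposite way to its inclusion level. The largest decreases were in Ybx1 (1.0 to 0.0), Ccnb1 (1.0 to 0.07), Tpt1 (1.0 to 0.11), Atp5l (0.99 to 0.12), Tarbp2 (0.98 to 0.18), Rtn4 (0.94 to 0.15), Ube2v1 (0.82 to 0.04), Depdc1a (0.99 to 0.22), Pprc1 (0.99 to 0.23) and Srp9 (0.73 to 0.01). The level of Ybx1 does not follow its distinguishing reads, which were 27 for inclusion and 2 for skipping against 7426 and 0 in WT. How this level arose from the reads could not be examined. The same holds for Rtn4, whose distinguishing reads were almost all for inclusion in both libraries, 1261 and 3 against 7529 and 0 in WT. Of the 10 largest decreases 7 had 0 skipping reads in WT, and Morf4l1, Rbm3 and Eif4a3 had 0 after knock-down. With the null odds ratio set by exon length, the split was 103 higher and 265 lower.

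Of 82 exons of hnRNP genes and other splicing regulators 10 were called higher, 16 lower and 56 not called, 29 when adjusted over the list alone, at percentile 99.9, with Syncrip, an hnRNP, falling from 0.94 to 0.41 and Hnrnpr from 0.75 to 0.37. The random lists were not matched on inclusion level in WT. Its median was 0.77 in exons called lower and 0.435 in those called higher, against 0.92 in random sets of tested exons. The percentiles are therefore not separated from the WT levels of the listed exons. SR protein exons were 1 higher (Srsf1, 0.74 to 0.98), 9 lower with Tra2a among them, and 34 not called, 11 when adjusted over the list alone (percentile 91.7). Chromatin regulators were 3 higher, 14 lower and 84 not called, 17 when adjusted over the list alone (percentile 95.8), with lower inclusion in Mtf2, a Polycomb accessory protein (0.80 to 0.28), and the remodeller Bptf (0.76 to 0.32). Higher were Jarid2, another Polycomb accessory protein (0.76 to 0.95), and the bromodomain genes Brd2 (0.49 to 0.68) and Brd8 (0.46 to 0.84). For Brd8 the reads, 386 and 17 against 508 and 0 in WT, point the opposite way to its level. The cytoskeleton list gave 3 higher (Nf2, Clstn1 and another exon of Ctnnd1), 17 lower and 131 not called, 20 when adjusted over the list alone (percentile 61.4).

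The single knock-downs were compared with WT to separate the 3 proteins, and exons of Morf4l1, Tra2a and Ctnnd1 were called in each. Morf4l1 stood at 0.93, 0.95 and 0.91 in the HP1alpha, HP1beta and HP1gamma knock-downs against 0.10 in WT, Tra2a at 0.10, 0.10 and 0.08 against 0.68, and Ctnnd1 at 0.07, 0.04 and 0.08 against 0.67. A 15-nucleotide exon of Immt, a subunit that shapes mitochondrial cristae (chromosome 6, 71866726 to 71866740), stood at 0.82 in the HP1alpha, 0.28 in the HP1beta, 0.83 in the HP1gamma and 0.33 in the triple knock-down against 0.0 in WT. Commd6 stood at 0.92, 0.95 and 0.18 in the HP1alpha, HP1beta and HP1gamma knock-downs against 0.03 in WT, and Adgrl1 at 0.89, 0.91 and 0.56 against 0.02. Fgfr2, a fibroblast growth factor receptor (chromosome 7, 130198419 to 130198563), stood at 0.23, 0.42 and 0.42 against 0.98. Brd8 again had reads opposite to its level in the HP1gamma knock-down (549 and 12 against 508 and 0). Calls numbered 99 higher and 614 lower of 6048 exons for HP1alpha, 110 and 567 of 5724 for HP1beta, and 83 and 510 of 5183 for HP1gamma. For hnRNP and other splicing regulators 8 exons were higher, 19 lower and 68 not called for HP1alpha, 28 when adjusted over the list alone (percentile 99.4). The counts were 9, 19 and 64 for HP1beta, 28 when adjusted over the list alone (percentile 99.95), and 7, 19 and 60 for HP1gamma, 27 when adjusted over the list alone (percentile 93.2).

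Few differences were detectable between the knock-downs themselves. Over 4313 exons read in all 7 libraries and thinned to equal depth, 0 to 1 exons were called between any 2 knock-down libraries of WT cells, against 253.9 to 346.9 between a knock-down and an untransfected library and 62.9 between TKO and WT. At full depth the numbers were 0 to 1, 457 to 687 and 219. The short exons of Commd6 and Adgrl1 had too few reads in some libraries to enter these counts. The differences of the HP1alpha and HP1beta knock-downs from WT had Pearson's r of 0.925 across exons and a covariance of 0.0203. Libraries simulated without change, sharing 1 redrawn WT library, gave 0.710 and 0.00636. Called the same way in both knock-downs were 511 exons, against 59.5 for independent lists. The simulation gave 0, but it held no changed exon and its test allowed for the platform shift. That 0 was close to fixed in advance and is no measure for the 511. These comparisons share the 1 WT library and the platform contrast, so part of the excess may come from both. The median difference in inclusion depended on exon length in these comparisons. For the triple knock-down it was -0.005 in the shortest eighth of exons (at most 62 nucleotides) and -0.08 in the longest (at least 219), whereas between TKO and WT it was 0 in every eighth.

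**Figure D2:**
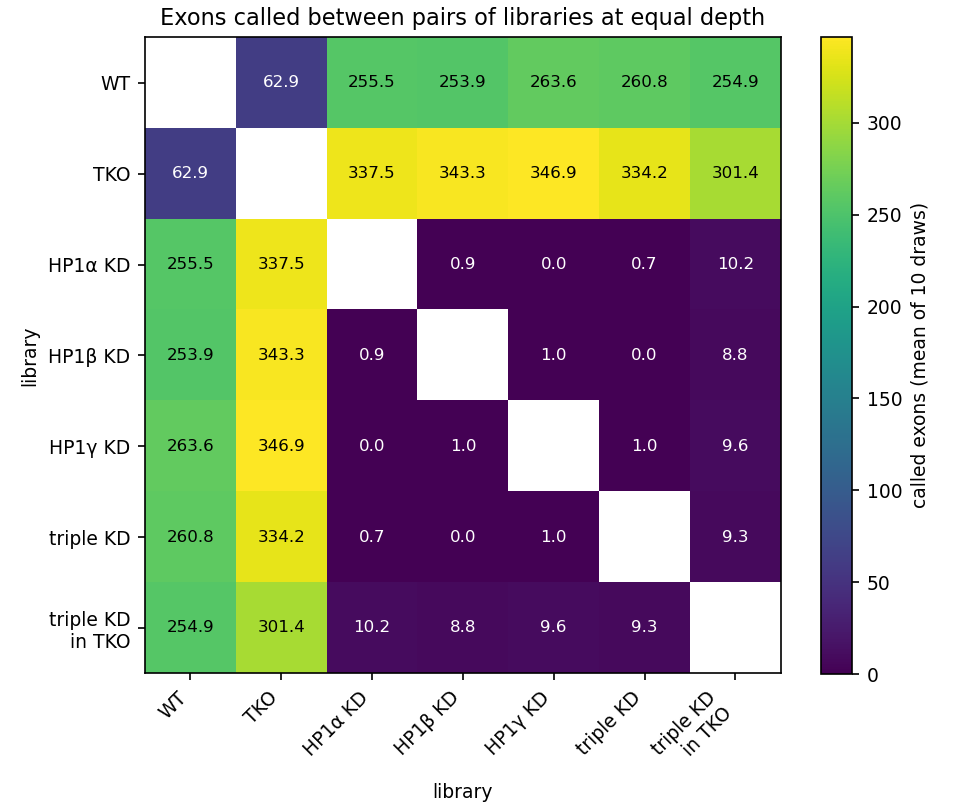
Heat map of the number of exons called between each pair of the 7 libraries at equal depth (mean of 10 thinning draws over 4313 exons; colour and printed number both give the count). Knock-down libraries of WT cells differ from one another in 0 to 1 exons and from the untransfected libraries in 253.9 to 346.9.

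**Figure D3:**
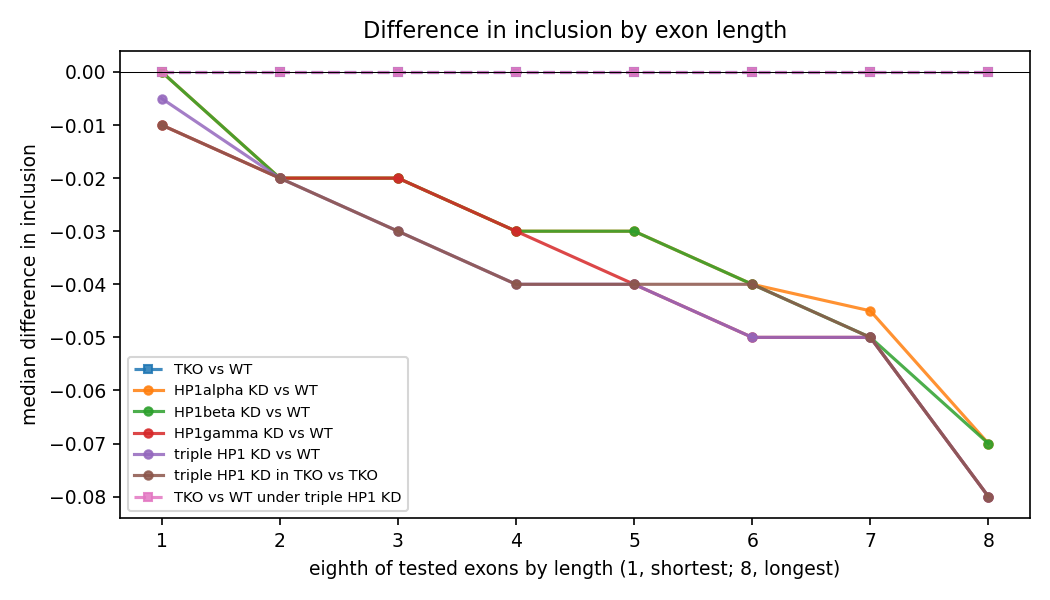
Median difference in inclusion level (vertical axis, 0 to 1 scale) in each eighth of tested exons ordered by length (horizontal axis), 1 line per comparison. The triple knock-down against WT goes from -0.005 to -0.08, and TKO against WT stays at 0.

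The triple knock-down in cells without DNA methyltransferases, compared with TKO, was led by exons also called in WT cells. Morf4l1 stood at 0.91 against 0.10, Rps24 at 0.84 against 0.15, Rbm3 at 0.77 against 0.12, Tra2a at 0.13 against 0.74 and Ctnnd1 at 0.10 against 0.69. Exons of hnRNP genes changed in both directions, with lower inclusion in Hnrnpa2b1 (chromosome 6, 51461920 to 51462055; 0.10 against 0.53, adjusted p = 3.63e-176 by Fisher's exact test) and higher inclusion in Hnrnpc (chromosome 14, 52098015 to 52098040; 0.58 against 0.16, adjusted p = 7.29e-68). An exon of Cbx3, the HP1gamma gene, stood at 0.30 (0.19 to 0.46) against 0.92 (0.90 to 0.94). The same exon stood at 0.47 (0.30 to 0.67), 0.20 (0.13 to 0.29), 0.57 (0.24 to 0.93) and 0.45 (0.20 to 0.85) in the HP1alpha, HP1beta, HP1gamma and triple knock-downs of WT cells. In WT it stood at 0.99. No exon of an HP1 gene was called in those comparisons with WT. For the HP1gamma and the triple knock-down, however, only 2 of the 3 HP1 genes had an exon with enough distinguishing reads to be tested. Where an exon was not tested, the absence of a call says nothing about it. Of 5188 exons 68 were called higher and 568 lower, and 80 and 358 with the null odds ratio set by exon length. Of 483 exons called for the triple knock-down in WT cells and tested here, 455 moved the same way, 290 were called in both (47.6 for independent lists) and 0 were called in opposite directions. For hnRNP and other splicing regulators 5 exons were higher (in Rbm3, Hnrnpc, Ptbp1 and Rbm39), 15 lower and 65 not called, 22 when adjusted over the list alone (percentile 97.9). For chromatin regulators 4 were higher (in Jarid2, Brd2, Brd3 and Mta1), 9 lower and 86 not called, 13 when adjusted over the list alone (percentile 96.7).

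Whether the difference between TKO and WT cells persists when HP1 is targeted was examined by comparing TKO with WT under the triple knock-down. Lmo7, which links adherens junctions to actin (chromosome 14, 101931172 to 101931280), was included at 0.16 (0.10 to 0.24) in TKO and 0.76 (0.57 to 0.92) in WT, with adjusted p = 1.24e-07 by Fisher's exact test. The Immt exon stood at 0.01 (0 to 0.02) against 0.33 (0.25 to 0.42), with adjusted p = 2.29e-11 in the same exact test, but ranged from 0.28 to 0.83 over the 4 knock-downs of WT cells, more than this pair differed. Inclusion was higher in TKO in Depdc1a (0.73 against 0.22), Tjap1 (0.68 against 0.21), Usp1, a deubiquitinase of DNA repair (0.71 against 0.33), and Mtmr3, a phosphoinositide phosphatase (0.56 against 0.28). It was lower in Rbm27 (0.64 against 0.94) and Atp13a3 (0.19 against 0.44). Without knock-down the exons of Lmo7 (0.73 in TKO against 0.72 in WT), Immt (0.0 in both), Depdc1a (1.0 against 0.99), Tjap1 (0.58 against 0.61) and Rbm27 (0.74 in both) were not called between TKO and WT. An exon of the fibronectin gene Fn1 (chromosome 1, 71613763 to 71614035) stood at 0.65 (0.60 to 0.70) against 0.48 (0.43 to 0.53), and a second Hnrnpa2b1 exon (chromosome 6, 51464428 to 51464547) at 0.36 (0.34 to 0.37) against 0.51 (0.49 to 0.55).

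Of 4473 tested exons 11 were called higher and 10 lower, 0.469% together (exact 95% interval 0.291 to 0.717), and 237 had an unadjusted p under 0.05. The triple knock-downs were unequal in Cbx1, at the ratios of 0.352 in WT cells and 0.641 in TKO cells given above, which this comparison does not separate from the cell line. In simulated data 25 of 100 changes of 0.2 in the share of inclusion reads were recovered in this comparison. In TKO against WT 46 of 100 were recovered. Of 209 exons called between untransfected TKO and WT and tested here, 143 moved the same way, 58 the opposite way and 8 did not move. Among the exons that moved, the same-direction share was 71.1% (exact 95% interval 64.3 to 77.3). Their median difference in the direction of the untransfected pair was 0.16 in that pair and 0.04 here. Selection for a large difference in the first pair by itself lowers the second value. Of 20 exons called here and tested in the untransfected pair, 15 moved the same way and 3 the opposite way, with medians of 0.195 here and 0.10 there. Of the 134 exons with reads of both classes in WT and TKO, 99 moved the same way and 30 the opposite way, 76.7% of those that moved. Of the 75 without, the numbers were 44 and 28, 61.1% of those that moved. Exons of 6 genes and 1 exon shared by the overlapping genes Cdk2 and Pmel were called in both pairs, all in the same direction. They are named because they were called in both, after their values were seen. Usp1 (chromosome 4, 98926455 to 98926674) rose from 0.71 to 0.93 without and from 0.33 to 0.71 with the knock-down, Mtmr3 from 0.41 to 0.62 and from 0.28 to 0.56, Faim from 0.11 to 0.23 and from 0.03 to 0.13, and the Cdk2 and Pmel exon from 0.50 to 0.61 and from 0.24 to 0.41. Ehmt2, a histone H3 methyltransferase (chromosome 17, 34905610 to 34905711), fell from 0.42 to 0.23 and from 0.30 to 0.20, Mfge8, a secreted glycoprotein, from 0.20 to 0.04 and from 0.52 to 0.28, and Atp13a3 from 0.44 to 0.31 and from 0.44 to 0.19.

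**Figure D4:**
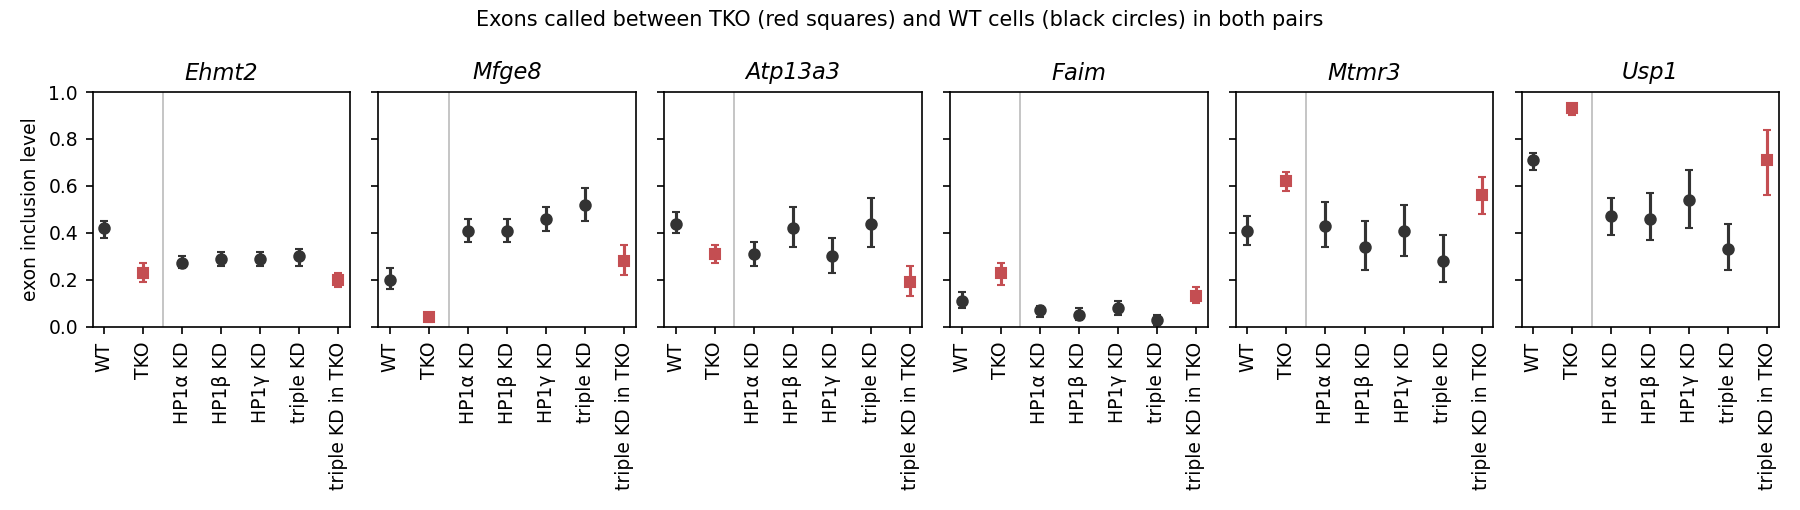
Inclusion level (0 to 1, with deposited intervals as error bars) of exons of Ehmt2, Mfge8, Atp13a3, Faim, Mtmr3 and Usp1 (1 panel each) in the 7 libraries; red squares are TKO cells, black circles WT cells, and a line separates untransfected from knock-down libraries. Usp1 goes from 0.71 to 0.93 between untransfected WT and TKO and from 0.33 to 0.71 between the triple knock-downs.

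Under the triple knock-down the lists held few calls. For hnRNP and other splicing regulators 3 exons were lower, 2 of Hnrnpa2b1 and 1 of Rbm27, and 77 not called, 3 when adjusted over the list alone (percentile 59.6). For the cytoskeleton list, Epb41l1 (0.21 against 0.02) and Fn1 were higher, Slk (0.02 against 0.19) lower and 141 not called, 4 when adjusted over the list alone (percentile 85.1). Of the chromatin regulators Ehmt2 was lower and 91 exons were not called, 1 when adjusted over the list alone (percentile 51.6), and of 44 SR protein exons none was called, 0 when adjusted over the list alone (percentile 67.1).

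Whether the difference between triple knock-down and untransfected libraries depended on the cell line was tested with Zelen's exact test of equal odds ratios. That difference joins knock-down, transfection and platform. Kmt5a, a histone H4 methyltransferase (chromosome 5, 124445969 to 124446084), had inclusion of 0.35 in WT and 0.32 after the triple knock-down, against 0.23 in TKO and 0.53 after it, a difference of log2 odds ratio of 9.44 (adjusted p = 3.69e-14, Zelen's exact test). Tpm3, a tropomyosin (chromosome 3, 90091013 to 90091091), went from 0.10 to 0.09 in WT cells and from 0.28 to 0.09 in TKO cells (-10.18, adjusted p = 1.03e-10, exact test). Slc39a14, a zinc transporter, went from 0.66 to 0.98 and from 0.93 to 0.81 (-9.81, adjusted p = 0.00226, exact test). The odds ratios rest on distinguishing reads, which the levels need not follow. In WT the Kmt5a exon had 157 inclusion and 0 skipping reads at a level of 0.35. In TKO the Tpm3 exon had 238 and 0 at a level of 0.28. Of 4344 tested exons 117 were called, with no minimum difference in level, 35 with a higher odds ratio in TKO cells and 82 with a lower one, and 343 had an unadjusted p under 0.05. Of the 117, 72 had a difference of differences in inclusion of at least 0.1, and 58 lacked inclusion or skipping reads in WT or TKO. Of the same 117, 46 were also called in TKO against WT, and 6 in the same comparison under the knock-down. The test does not separate the cell line from the unequal Cbx1 ratios of the triple knock-downs (0.352 in WT cells, 0.641 in TKO cells).

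The overlap of the exons that differed in TKO and in the triple knock-down, both against WT, was counted over 4525 exons tested in both, with p adjusted over these exons. Higher in both were 16 exons (3.08 by chance overlap of independent lists), lower in both 19 (5.89), and opposite 38 (17.2). Libraries simulated without change, sharing 1 redrawn WT library, gave 0 in common. They held no changed exon and their test allowed for the platform shift, so that 0 was close to fixed in advance. Across exons, which are not independent replicates, Pearson's r of the differences was 0.165 and Spearman's rho 0.147, against a simulated Pearson's r of 0.338, and the covariance was 0.00175 against a simulated 0.00239. With the WT reads split into separate parts, 18 exons were called the same way in both (4.66 by chance), 26 the opposite way (10.1 by chance), and r was 0.0926. There is 1 WT library, so part of the excess in the same direction may come from the shared control. A shared control does not by itself add opposite calls, which also exceeded independent lists, and the source of that excess was not tested. The simulation drew distinguishing reads only, which the deposited levels need not follow.

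Exons with lower inclusion in the triple knock-down had a median length of 129 nucleotides against 117 in random sets of tested exons (percentile 99.95), and those with higher inclusion 97 (percentile 0.33). In this comparison the median difference of all tested exons already moved with length, from -0.005 to -0.08, so these lengths are not a trait of the called exons alone. Exons higher in TKO against WT had a median of 103 nucleotides against 111 (percentile 5.09) and those lower in TKO 102 (percentile 10.4). Of the exons lower in TKO 57.9% had a length divisible by 3 (percentile 98.9).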

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

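The tests of depth and of counting error, and the sign test of the exons without skipping reads, were planned; those of HP1 paralog differences, of read length, of missing read classes (alone and with depth), the searches for libraries of a matching platform, and the counts of genes listed in TKO libraries alone were chosen only after the result was seen.

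The difference between triple knock-down and untransfected libraries differed between WT and TKO cells, by Zelen's exact test, at 117 of 4344 exons. It joins knock-down, transfection and platform. Of the 117, 72 had a difference of differences in inclusion of at least 0.1. Of the same 117, 46 were also called between untransfected TKO and WT, and 6 between TKO and WT under the knock-down. Among the exons named by rule, the difference of log2 odds ratio was 9.44 for Kmt5a, 8.08 for Kxd1, 7.69 for Rnf181, 7.55 for Rtn4 and 7.34 for Chchd7. It was -10.18 for Tpm3, -9.81 for Slc39a14, -9.48 for Bex1 (overlapping LOC115489115), -9.44 for Abcc5 and -8.21 for Rps27l. Each of the 10 has a library without a read of one class, and Rtn4 had levels of 0.94 and 0.15 in WT cells and 0.96 and 0.15 in TKO cells. Of the 117, 56 had reads of both classes in all 4 libraries.

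Fewer exons separated TKO from WT under the triple knock-down than without it. Thinned to the reads of the knock-down pair, the untransfected pair still gave 93.8 called exons (draws 90 to 104) against 20 over the same 4344 exons, which argues against lower depth as the whole cause. Over 1579 exons with reads of both classes in WT and TKO it gave 161 against 23, and 72.4 (draws 67 to 83) against 23 when thinned as well, which argues against missing read classes, alone or with depth. Dependence on HP1 of the difference between TKO and WT cells stays open as a candidate explanation, as does a difference between the platforms. The reason is that 0 untransfected TKO and WT libraries were sequenced on the platform of the knock-downs. The siRNA doses, which differed between WT and TKO cells, also remain open and untested. Event reads of Cbx1 stood at a ratio of 0.352 in the triple knock-down of WT cells and 0.641 in that of TKO cells. Both ratios are to single knock-downs of WT cells that did not target Cbx1. Cbx5 (0.522 and 0.468) and Cbx3 (0.710 and 0.691) were closer. An unequal loss of HP1beta is therefore not separated from the cell line.

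Between 457 and 687 of 4313 exons separated a knock-down from an untransfected library. An effect that differs between loss of HP1alpha, HP1beta and HP1gamma is argued against for these differences as a whole, since at equal depth the pair of single knock-downs that differed most had 1 exon called, 0.394% of the 253.9 called for the single knock-down closest to WT. Immt goes the other way, called between HP1beta and each of the others (0.82, 0.28 and 0.83 in that order), while Commd6 (0.92, 0.95 and 0.18) had too few reads after HP1gamma knock-down to be tested and Adgrl1 (0.89, 0.91 and 0.56) was not called between single knock-downs. Read length and platform may account for part of it: the median difference moved by -0.07 or further from the shortest to the longest eighth of exons in all 5 comparisons of a knock-down with untransfected cells, and by 0 between TKO and WT. A loss of HP1 proteins common to all knock-downs, or transfection, cannot be told apart from platform, as there were 0 pairs of a knock-down and an untransfected or control library of one platform.

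Some exons had no skipping read in one untransfected library and at least 10 in the other. There were 245, of which 84 had none in WT and 161 none in TKO, whereas 100 draws from a common inclusion share gave at most 4, which argues against counting error. Between the 10 pairs of the shallower knock-down libraries there were 0 to 7. A change in splicing between TKO and WT stays open: 54.7% of 148 of them (81 exons, exact 95% interval 46.3 to 62.9) moved the same way between the triple knock-down libraries, but the planned bound of 50% decides nothing, as those libraries are shallower and a change that needs HP1 would be absent there. A difference in junction detection between the libraries is a candidate explanation that was not tested.

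The number of event reads per gene, which the splicing comparisons do not test, also differed. The median log2 ratio of TKO to WT was 0.55 over 7 genes of the germline list and 1.25 over 5 of the differentiated and fibroblast list, against 0.12 over all genes. In addition 36 genes had a listed event in both TKO libraries and in none of the 5 libraries of WT cells. Over the 4 untransfected and triple knock-down libraries, 39 genes were listed in both of TKO cells and neither of WT cells, and 2 the other way, with fewer event reads in the triple knock-down of WT cells (4677236) than of TKO cells (7571677).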

How the results depend on the processing

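The settings with a read of each class in each library, with a null odds ratio set by exon length, and with read odds in the same direction were chosen only after the data were seen. No paired analysis was possible because the authors pooled the replicates before deposit, so neither a block nor leaving out a replicate could be run. Of 139 named exons in their comparisons, 27 were tested in every alternative and kept direction and call in each. Counting only the alternatives that tested an exon, 91 did so, and 3 reversed in any. A read of each class in each library left 79 of the 139 untested, a minimum of 50 reads 56, and exons that pass in all 7 libraries 43. Of 146 alternative counts, correlations and percentiles for 26 results, 99 were the same. Scaling event reads to exons listed in all 7 libraries moved every gene-list median by one constant, -0.01 or 0.02 on the log2 scale, and so tests nothing about the lists' order. The cause was not tested except where a setting leaves fewer exons or reads. In the order TKO, HP1alpha, HP1beta, HP1gamma, triple knock-down, triple knock-down in TKO, and TKO against WT under knock-down, a difference of at least 0.2 left 147, 425, 397, 342, 297, 384 and 11 exons. Thinning to the shallowest library left 64.6, 257.1, 250.5, 263.2, 264.0, 300.7 and 10.2 of 4313 exons, so depth limits every count. Thinning to equal reads left 395.1 for HP1gamma, 297.9 for the triple knock-down and 11.3 under knock-down. With intervals apart in place of the test the counts were 1114, 1084, 1001, 861 and 1013 for the 5 knock-down comparisons and 71 under knock-down. With a log2 odds ratio of at least 1 they were 618 for TKO, 1088, 1030 and 894 for the single knock-downs and 972 for the triple knock-down in TKO. Exons that pass in all 7 libraries gave 219 for TKO, and a false discovery rate of 0.01 gave 11 under knock-down. For the dependence on cell line, a difference of differences of at least 0.2 left 35, thinning to equal reads 35.2, thinning to the shallowest 39.3 and a read of each class in each library 67, while a difference of differences above 0.1 with no test gave 760. Exons called in both TKO and triple knock-down numbered 18 with WT reads split (r = 0.0926). Comparisons without a shared library gave 290 for the triple knock-down in WT and in TKO (r = 0.787), and 8 for TKO against WT with and without knock-down (r = 0.119), adjusted over the exons tested in both. The comparisons behind the 290 still share the contrast of platform and transfection. Percentiles at a difference of 0.2 were 0.305 for the length and 90.1 for lengths divisible by 3 of exons lower in TKO, 2.70 for the length and 1.96 for the downstream intron of exons higher in the triple knock-down, and 98.9 for the downstream intron of exons lower in it. Against matched exons, lengths divisible by 3 of exons higher in the triple knock-down lay at 89.1. By read odds Brd8 reversed to -4.53 (HP1gamma) and -5.53 (triple knock-down) and Tdh to -4.39 on the log2 scale, and with the null set by exon length to -4.42 (Brd8) and -4.15 (Tdh, triple knock-down), since skipping reads were seen only after knock-down.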

Other observations

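The test of the germline list was planned; the count of genes listed only in TKO libraries, and the genes named here from it, were chosen only after the values were seen.

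More germline genes were listed in TKO than in WT. Of the germline list, 13 genes had an event of at least 100 reads in TKO and 7 in WT. Present in TKO and not in WT were Dazl, a germ cell RNA-binding protein (1203 reads), Asz1, a germ cell factor of transposon silencing (582), Piwil4, a PIWI protein (114), Rhox2a (1095), Xlr3a (4707) and Xlr5a (6758), the last 3 uncertain as members of near-identical families. No germline gene was listed in WT and not in TKO, while over all genes 256 were listed in TKO and not in WT and 138 in WT and not in TKO. Fkbp6, a meiotic gene, had 1508 reads against 195 (log2 ratio 2.99) and Hormad1, of the meiotic chromosome axis, 269 against 115 (1.27), but Sycp3, of the synaptonemal complex, had 174 against 616 (-1.78). Among the 36 genes listed in both TKO libraries and in no WT library were the endoderm factor Sox17 (369 reads in TKO and 134 after the triple knock-down), the homeobox gene Meis1 (241 and 184), the macrophage factor Spic (275 and 181), the interferon-inducible gene Ifi35 (12301 and 172), the immunoproteasome gene Psmb9 (130 and 131) and the meiotic gene Hormad2 (371 and 166).

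Of the 40 differentiated and fibroblast markers, only 5 had an event in both untransfected libraries, and these had more event reads in TKO. The median log2 ratio over the differentiated and fibroblast list was 1.25 at percentile 100.0 of random lists, with all 5 genes above 0, among them the basement membrane collagen Col4a1 (2.40), the eye and neural factor Pax6 (1.97) and the imprinted gene Mest (1.12). Under the triple knock-down the median over 3 genes was 0.93 at percentile 99.7, with 2 of the 3 above 0. The pluripotency list had a median of 0.02 (percentile 33.0) without knock-down and -0.65 (percentile 0.67, 2 of 8 genes above 0) with it, with Klf4 at -1.01, Tbx3 at -1.37 and Sall4 at -0.96, against a median of -0.11 over all genes. The cytoskeleton, adhesion and polarity list stood lower among random lists under the knock-down, with a median of -0.43 (percentile 0.01, 17 of 68 genes above 0), against 0.12 (percentile 68.0) without it. For hnRNP and other splicing regulators the medians were -0.12 (percentile 0.96) and -0.36 (percentile 0.53), and for SR proteins -0.14 (percentile 7.22) and -0.36 (percentile 1.75). Across 3254 genes, which are not independent replicates, Pearson's r between the log2 ratios of the untransfected and the knock-down pair was 0.412 and Spearman's rho 0.370. Dmtn, which bundles actin, was more than 4-fold lower in TKO in both pairs (-2.27 and -2.67), and is named after its values were seen.

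A hypothesis was that germline transcripts silenced by promoter methylation may be higher in cells without DNA methyltransferases. Their median log2 ratio of 0.55 lay at percentile 97.45 of random lists in the untransfected pair, with 6 of 7 genes above 0. The knock-down pair held 2 genes of the list in common, too few for a percentile, so the hypothesis stays open.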
